A study of Saccharomyces cerevisiae with 36 samples.

How the data were processed

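The data were total RNA sequencing libraries of the budding yeast strain BY4742, 36 in number, from 4 strains at 3 times with 3 replicates lettered A, B and C. Per the labels' protocols, cells were grown in rich medium at 25 °C to mid-log phase, pre-warmed medium brought them to 42 °C, and RNA was taken by acid phenol and chloroform extraction. The duration label holds 0, 10 or 45 without a unit and was read as minutes, since the treatment text names a harvest at 45 min. Per the submitters' processing notes, the authors aligned reads with HISAT2 2.1.0 to genome build R64 and made the deposited count values with HTSeq, whose version and strand setting were not given in the sources used here. The deposited files gave 1 whole-number count for each of 6600 open reading frames and 5 summary lines for reads outside features, ambiguous reads, low-quality alignments, unaligned reads and reads aligned to several places. The summary lines stayed out of library sizes and gene tests. Of the 6600 identifiers, 5917 matched locus tags of the reference annotation, all of them protein-coding, and 683 did not.

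The files held no entries for small nucleolar RNAs or other stable non-coding RNAs, so 2 fixed lists of 76 and 13 such genes had 0 members to test and were not analysed here. Of 10 mitochondrially encoded genes 8 were in the files and 6 had any counts, and of 5 auxotrophic marker genes 3 had counts, and neither list was tested as a set. Strand was checked with 8 genes nested inside a gene of the opposite strand, of which 7 had counts. The inner and the outer gene had 95587 and 138 counts for CPP2, 5686 and 257 for ADF1, 3001 and 1247 for YJL077W-A, 3285 and 6732 for NAG1, 228 and 17097 for VAM10, 44 and 11631 for SLM6, 20 and 22857 for YIL105W-A, and 0 and 130 for YER190C-B. A read inside a nested gene overlaps both genes, so counting without regard to strand would call it ambiguous. CPP2 and ADF1 had counts in all 36 libraries, which argues against such counting at the gene positions of the reference annotation. The pair with 0 inner counts decided nothing.

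The tests, comparisons, gene lists and most alternatives were chosen before the data were examined. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15, smallest group 3), which left 6017. Libraries were scaled by the trimmed mean of M values (TMM), with factors from 0.618 to 1.388, and edgeR 4.0.16 fitted a quasi-likelihood model with 1 coefficient for each of the 12 groups, with a common biological coefficient of variation of 0.1535. Benjamini-Hochberg adjustment ran over all genes of each comparison at a false discovery rate of 0.05. The 30 comparisons were heat at 10 and 45 min against 0 min in each strain, each deletion strain against WT at each time, the double deletion against each single deletion at each time, heat responses of each single deletion against that of WT, and the departure of the double deletion from additivity. Log2 CPM values, used for list levels, list tests and principal components, had a prior count of 2, and fold changes were those of the fit. Lists were tested with camera in limma 3.58.1 with a correlation of 0.01 between genes, adjusted over the lists, and again with an estimated correlation. Calls that held with an estimated correlation were meiosis genes in all 8 heat comparisons, ergosterol genes in 16 comparisons, phosphate genes in 5, cell wall integrity targets in 3, Gcn4 targets in 3 and histones in 2. No call of any other list held in that way.

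The alternatives were DESeq2 1.42.0, no low-count filter, a mean of at least 5 CPM, DESeq2's size factors in edgeR, total counts only, protein-coding genes only, only the samples of the comparison, replicate letters as a block, and leaving out 1 library at a time. Removing both heated double-deletion libraries of letter C was added after the data were seen, because these libraries stood apart from their replicates. Genes named in the text were SLT2 and RRP6, up to 5 rising and 5 falling genes per comparison among called protein-coding genes with a mean of at least 5 CPM and separated groups, up to 4 called and 2 uncalled members of each list, and a fixed set of genes written before the values were seen. No fold is given where a group had 0 counts in all its libraries. One gene that the rule allows is not reported here. Exact permutation tests of 3 against 3 libraries cannot give a two-sided p below 0.1, and for any single gene the chance that 2 such groups do not overlap is 10%.

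Replicate letters pair in a comparison when all same-letter correlations exceed 0.1, which held in 5 of the 30 comparisons, with values of 0.154, 0.117 and 0.106 for the mpk1Δ strain against WT at 0 min and 0.198, 0.285 and 0.148 at 45 min. For the double deletion against WT they were 0.177, 0.129 and 0.208 at 0 min, 0.104, 0.478 and 0.5 at 10 min, and 0.177, 0.217 and 0.154 at 45 min. The overlap of the mpk1Δ and rrp6Δ effects against the same WT libraries was compared with 10 simulated draws at each time in which only the controls were shared. Overlaps of either effect with that of the double deletion against WT share the same controls and were not simulated. Counted reads were 2235918 in the smallest library and 12072112 in the largest. A count of 3 corresponds to 0.2485 to 1.342 CPM, and such floors cover counting error only, since reads copied by PCR were counted without molecular identifiers.

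The model was tested on simulated data made from 5970 genes. In a simulation of the mpk1Δ strain against WT at 45 min, 26 of 50 genes changed 1.5-fold were called, 42 of 50 at 2-fold and 50 of 50 at 4-fold, with 3 false calls. In a simulation of a difference between heat responses the calls were 11, 31, 45 and 49 of 50 at 1.5, 2, 4 and 8-fold with 0 false calls. For the mpk1Δ strain against WT at 0 min, simulated with no change put in, 0 genes were called. Work ran in R 4.3.3 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.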

Results

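Total RNA was sequenced from the yeast Saccharomyces cerevisiae, laboratory strain BY4742, before and after a shift from 25 °C to 42 °C. The 4 strains were the wild type (WT), a strain lacking MPK1, a strain lacking RRP6 and a strain lacking both genes, called the double deletion here. MPK1, listed as SLT2, encodes the last kinase of the cell wall integrity pathway. RRP6 encodes a nuclease of the nuclear exosome, the complex that trims and degrades nuclear RNA. Each strain was sampled at 0, 10 and 45 min, with 3 libraries per strain and time that the series design calls biological replicates. This gave 12 groups and 36 libraries. Reads counted to genes ranged from 2235918 to 12072112 per library, and 6017 genes passed the low-count filter. Values given below as log2 fold changes carry the standard error (SE) of the fit, with n = 3 libraries per group. A gene or list member is said to have risen or fallen when it passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested.

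The deleted genes matched the strain labels. SLT2 (YHR030C, chromosome VIII, 168890 to 170344, build R64) had a total of 6 counts over the 18 libraries of strains lacking it, with 13 of them at 0, against 111 to 1780 counts in each of the other 18 libraries. RRP6 (YOR001W, chromosome XV, 326832 to 329033) had a total of 2 counts over its 18 deleted libraries, 16 of them at 0, against 40 to 1010 counts elsewhere. Among the auxotrophic marker genes, LYS2 and URA3 had 0 counts in all 36 libraries and LEU2 had 1, where 3 counts correspond to between 0.249 and 1.34 CPM, that is counts scaled to library size, depending on the library. HIS3 and MET17 were counted in every library, at 11.2 to 106 CPM and 18.7 to 242 CPM. The first principal component of the tested genes held 71.9% of the variance and the second 8.14%. Replicates of a group correlated across genes with r of at least 0.954, the lowest value being that of replicates B and C of the double deletion at 45 min.

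The first question was what heat did to WT cells. After 10 min at 42 °C, HSP26, encoding a small heat shock protein, rose by 10.15 ± 0.39 on the log2 scale, and SSA4, encoding a heat-inducible Hsp70 chaperone, rose by 9.91 ± 0.37. SSA4 went from 36 ± 5.87 CPM (SD, n = 3) at 0 min to 34640 ± 1657 CPM at 10 min, with edgeR's adjusted p = 1.41e-19 and every heated library above every unheated one. TMA10 rose by 9.79 ± 0.58, HSP42, encoding another small heat shock protein, by 9.18 ± 0.53, and HSP104, encoding the disaggregase, by 7.88 ± 0.34. All 27 chaperone genes regulated by the heat shock factor Hsf1 rose, 27 adjusted over the list alone, with a median of 4.59. All 26 general stress genes driven by Msn2 and Msn4 rose, 26 adjusted over the list alone, with a median of 5.31, among them HSP12 at 8.56 ± 0.68 and the catalase gene CTT1 at 5.44 ± 0.48. These lists gave camera adjusted p of 9.6e-17 and 4.21e-16, with adjusted p = 0.125 and adjusted p = 0.0966 with an estimated correlation.

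At the same time all 33 ribosome biogenesis genes fell, 33 adjusted over the list alone, with a median of −3.12 (camera adjusted p = 4.6e-13, adjusted p = 0.24 with an estimated correlation). NSR1, which encodes a nucleolar protein of rRNA processing, changed by −5.14 ± 0.46, and the large-subunit assembly genes ALB1, NIP7 and BRX1 changed by −5.31 ± 0.33, −5.00 ± 0.37 and −4.91 ± 0.37. Of 137 cytosolic ribosomal protein genes, 108 fell and 2 rose, 111 and 2 adjusted over the list alone, with a median of −1.02 (camera adjusted p = 5.26e-08, adjusted p = 0.639 with an estimated correlation). Genes of the nuclear exosome and its cofactors fell in 17 of 19 cases and rose in 1, the same counts adjusted over the list alone (camera adjusted p = 4.53e-06, adjusted p = 0.065 with an estimated correlation). RRP6 itself stood at −2.73 ± 0.18 and the helicase gene MTR4 at −2.27 ± 0.28. Of 23 ergosterol biosynthesis genes, 18 fell and none rose, 18 adjusted over the list alone, led by ERG13 at −2.02 ± 0.18 (camera adjusted p = 0.000322, adjusted p = 0.065 with an estimated correlation). Of 25 cell wall integrity targets, 11 rose and 5 fell, 11 and 5 adjusted over the list alone, with a median of 0.25 that became −0.12 with total counts as the only scaling (camera adjusted p = 0.372). That scaling gave 11 rising and 12 falling targets. Their rising members included GSC2, encoding a glucan synthase subunit also called FKS2, at 3.65 ± 0.22, and PIR3, encoding a cell wall glycoprotein, at 3.18 ± 0.41. PST1 and CRH1 did not pass, at −0.15 ± 0.20 and −0.01 ± 0.17, nor did SLT2 at 0.08 ± 0.23. With total counts only, PST1 stood at −0.52 and CRH1 at −0.38, and both passed. In all, 2302 genes rose and 2179 fell, of which 1512 and 1109 changed at least 2-fold. Total-count scaling moved the median of all genes by −0.37 and gave 1680 higher and 2805 lower.

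WT cells at 45 min were compared with 0 min in the same way. HSP26 stood 12.47 ± 0.42 above its level at 0 min (edgeR adjusted p = 1.18e-20, all 3 heated libraries above all 3 unheated ones), SSA4 11.21 ± 0.39, HSP12 10.76 ± 0.73 and HSP104 9.08 ± 0.35. All 27 chaperone genes and all 26 general stress genes rose, 27 and 26 adjusted over the list alone, with medians of 4.95 and 6.36 (camera adjusted p = 1.52e-14 and 6.6e-14, adjusted p = 0.154 for both with an estimated correlation). Cytosolic ribosomal protein genes fell in 135 of 137 cases and rose in 1, the same counts adjusted over the list alone, with a median of −3.11 (camera adjusted p = 7.36e-21, adjusted p = 0.368 with an estimated correlation). RPL2A stood at −4.98 ± 0.45 and RPS1B at −5.01 ± 0.43. Ribosome biogenesis genes fell in 33 of 33 cases, 33 adjusted over the list alone, with a median of −2.94 (camera adjusted p = 4.36e-09, adjusted p = 0.368 with an estimated correlation). Ergosterol genes fell in 20 of 23 cases and rose in 1, the same adjusted over the list alone, with a median of −1.04 (camera adjusted p = 5e-05, adjusted p = 0.0284 with an estimated correlation). Genes of the unfolded protein response rose in 12 of 14 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.00311, adjusted p = 0.4 with an estimated correlation). The ER chaperone gene KAR2 stood at 5.55 ± 0.25 and the transcription factor gene HAC1 at 4.14 ± 0.17. Trehalose and glycogen genes rose in 8 of 10 cases and fell in 2, the same adjusted over the list alone, including the glycogen synthase gene GSY1 at 8.61 ± 0.43 (camera adjusted p = 0.00513, adjusted p = 0.327 with an estimated correlation). Of the cell wall integrity targets, 13 rose and 7 fell, 13 and 7 adjusted over the list alone, with a median of 0.43 that became −0.28 with total counts only (camera adjusted p = 0.364). Total counts gave 9 rising and 11 falling targets. GSC2 and PIR3 stood at 5.11 ± 0.23 and 4.46 ± 0.41. The totals were 2469 genes higher and 2358 lower, 1813 and 1522 of them by at least 2-fold. Scaling by total counts moved the median of all genes by −0.71 and gave 1618 higher and 3311 lower.

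**Figure D1:**
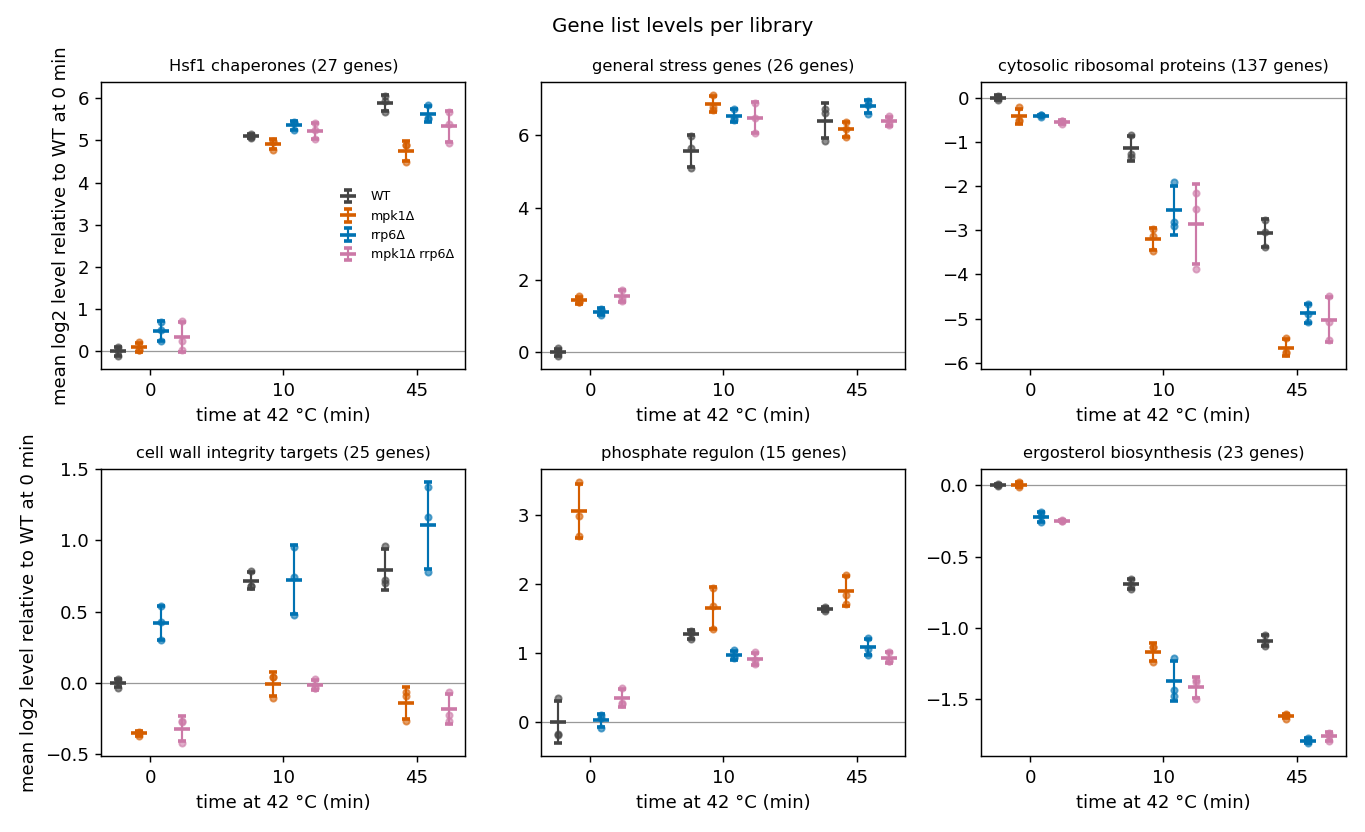
Mean log2 level of 6 gene lists in each of the 36 libraries relative to the WT mean at 0 min (vertical axis) against time at 42 °C in min, with strains in colours, dots for libraries and bars for the group mean ± SD (n = 3). Ribosomal protein genes stood at −3.06 in WT and −5.66 in the mpk1Δ strain at 45 min, and phosphate genes at 3.06 in the mpk1Δ strain at 0 min, while the median of the cell wall list in heated WT became −0.12 and −0.28 with total counts only.

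The same heat shift was then measured within each deletion strain. In the mpk1Δ strain, HSP26 rose by 10.27 ± 0.39 at 10 min and 11.06 ± 0.40 at 45 min, and SSA4 by 9.79 ± 0.37 and 9.82 ± 0.37. Chaperone genes rose in 26 of 27 cases at both times, 26 adjusted over the list alone at 10 min and at 45 min (camera adjusted p = 2.26e-16 and 6.27e-13, adjusted p = 0.173 and adjusted p = 0.2 with an estimated correlation). In the same strain ribosomal protein genes fell in 136 of 137 cases and rose in 1 at each time, the same adjusted over the list alone, with medians of −2.76 and −5.46 (camera adjusted p = 9.58e-25 and 5.94e-36, adjusted p = 0.267 and adjusted p = 0.227 with an estimated correlation). Phosphate regulon genes, which serve phosphate uptake and storage, fell in 12 of 15 cases and rose in 1 at 10 min, 12 and 1 adjusted over the list alone, with a median of −1.56 (camera adjusted p = 0.0014, adjusted p = 0.183 with an estimated correlation). The transporter gene PHO84 stood at −4.83 ± 0.60. Of 33 nuclear-encoded oxidative phosphorylation genes, 27 rose and 1 fell at 10 min, the same adjusted over the list alone, with a median of 1.12 (camera adjusted p = 4.81e-05, adjusted p = 0.338 with an estimated correlation). The strain had 2435 genes higher and 2219 lower at 10 min, or 1868 and 2671 with total counts only, which moved the median of all genes by −0.28. At 45 min it had 2554 higher and 2374 lower, where that shift was −0.12.

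In the rrp6Δ strain HSP26 rose by 10.51 ± 0.39 at 10 min and 12.45 ± 0.42 at 45 min, and SSA4 by 10.05 ± 0.37 and 10.41 ± 0.38. Ribosomal protein genes fell in 132 of 137 cases at 10 min and 136 at 45 min, with 1 rising each time, at medians of −2.10 and −4.63 (camera adjusted p = 1.27e-17 and 2.38e-31, adjusted p = 0.375 and adjusted p = 0.203 with an estimated correlation). Adjusted over the list alone, the falling members numbered 132 and 136. All 23 ergosterol genes fell at both times, 23 adjusted over the list alone, with adjusted p = 0.00713 and adjusted p = 0.00303 in camera with an estimated correlation. ALB1 changed by −5.03 ± 0.33 at 10 min, and the ribosomal protein genes RPL9A and RPS9B by −6.70 ± 0.57 and −6.57 ± 0.71 at 45 min. The totals were 2237 higher and 2266 lower at 10 min and 2436 and 2345 at 45 min. With total counts only, the median of all genes moved by −0.54 and −0.67 and the splits were 1380 and 3187, and 1508 and 3331.

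In the double deletion HSP26 rose by 10.55 ± 0.39 and 11.98 ± 0.41 at the 2 times, SSA4 by 9.86 ± 0.37 and 10.24 ± 0.38, and the hexose transporter gene HXT5 by 10.20 ± 0.55 at 10 min. Ribosomal protein genes fell in 135 and 136 of 137 cases, with 1 rising each time, at medians of −2.15 and −4.56 (camera adjusted p = 1.32e-21 and 1.48e-34, adjusted p = 0.293 and adjusted p = 0.19 with an estimated correlation). The falling members numbered 135 and 136 adjusted over the list alone. Ergosterol genes fell in 23 and 22 of 23 cases, 23 and 22 adjusted over the list alone, with adjusted p = 0.0035 and adjusted p = 0.00296 in camera with an estimated correlation. Oxidative phosphorylation genes rose in 22 of 33 cases and fell in 2 at 10 min, 22 and 2 adjusted over the list alone (camera adjusted p = 0.00305, adjusted p = 0.527 with an estimated correlation). Total counts alone gave 13 rising and 7 falling. The totals were 2246 higher and 2247 lower at 10 min and 2398 and 2283 at 45 min. Total-count scaling moved the median of all genes by −0.50 and −0.53 and gave 1420 and 3180, and 1590 and 3129.

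Loss of MPK1 was first compared with WT before heat, 3 libraries against 3. PHO84, which encodes the high-affinity phosphate transporter (YML123C, chromosome XIII, 24037 to 25800), rose by 6.39 ± 0.68, from 10.4 ± 15.8 CPM (SD) in WT to 789 ± 305 CPM in the mpk1Δ strain, with edgeR's adjusted p = 7.52e-08 and all 3 mpk1Δ libraries above all 3 WT libraries. The 3 WT libraries had 94, 13 and 2 counts of PHO84, or 28.6, 2.09 and 0.602 CPM, and without library A of WT the fold change was 8.98. The acid phosphatase genes PHO5 and PHO12 rose by 4.99 ± 0.24 and 4.91 ± 0.27, the phosphate cotransporter gene PHO89 by 4.96 ± 0.74 and the transport regulator gene SPL2 by 4.79 ± 0.41. Phosphate regulon genes rose in 14 of 15 cases, 15 adjusted over the list alone, with a median of 3.12 (camera adjusted p = 8.66e-31, adjusted p = 4.91e-06 with an estimated correlation). General stress genes rose in 20 of 26 cases, 21 adjusted over the list alone, with a median of 1.40 (camera adjusted p = 3.41e-20, adjusted p = 0.0932 with an estimated correlation). The hexokinase gene HXK1 stood at 3.31 ± 0.40 and DDR2 at 3.08 ± 0.62. Iron regulon genes rose in 9 of 16 cases and fell in 1, 11 and 1 adjusted over the list alone (camera adjusted p = 1.68e-05, adjusted p = 0.254 with an estimated correlation). The siderophore-binding wall protein genes FIT3 and FIT2 stood at 2.40 ± 0.41 and 2.37 ± 0.50. Cell wall integrity targets fell in 5 of 25 cases and rose in 1, 6 and 1 adjusted over the list alone (camera adjusted p = 0.000986, adjusted p = 0.33 with an estimated correlation), led by the wall protein gene CWP1 at −3.03 ± 0.41. Of 19 genes bound by the cell-cycle factors SBF and MBF, 8 fell, 9 adjusted over the list alone (camera adjusted p = 6.82e-06, adjusted p = 0.274 with an estimated correlation). Of these, 3 fell with total counts only. SSA4 and HSP104 did not pass, at −0.01 ± 0.27 and 0.64 ± 0.25, but HSP104 passed at 0.81 with total counts only and at 0.68 with only the 6 libraries compared. In total 601 genes rose and 314 fell. The count of 915 became 606 without replicate A of WT, 593 without replicate B of WT and 523 without replicate A of the mpk1Δ strain, and 2267 (1181 higher, 1086 lower) with only the 6 libraries compared. Total counts moved the median of all genes by 0.16 and gave 863 higher and 78 lower, DESeq2 gave 623 and 633, and DESeq2's size factors in edgeR gave 544 and 444.

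The mpk1Δ strain was next compared with WT after 10 min of heat. TDH1, encoding an isozyme of glyceraldehyde-3-phosphate dehydrogenase, stood 3.72 ± 0.55 above WT, the enolase gene ENO1 2.97 ± 0.49 and CTT1 2.33 ± 0.39. Ribosomal protein genes fell in 136 of 137 cases, 136 adjusted over the list alone, with a median of −2.09 (camera adjusted p = 3.03e-52, adjusted p = 0.179 with an estimated correlation). RPS9B stood at −2.67 ± 0.59 and RPS0B at −2.59 ± 0.46. Cell wall integrity targets fell in 15 of 25 cases and none rose, 16 adjusted over the list alone, with a median of −0.72 (camera adjusted p = 6.85e-06, adjusted p = 0.179 with an estimated correlation). These included the glucan synthase gene FKS1 at −1.41 ± 0.17, the chitin transglycosylase gene CRH1 at −1.31 ± 0.17 and PIR3 at −1.35 ± 0.33, for which edgeR's quasi-likelihood test gave adjusted p = 0.0013 with all 3 mpk1Δ libraries below all 3 WT libraries. General stress genes rose in 21 of 26 cases, 21 adjusted over the list alone, with a median of 1.38 (camera adjusted p = 2.21e-08, adjusted p = 0.239 with an estimated correlation). Oxidative phosphorylation genes rose in 27 of 33 cases and fell in 1, 30 and 1 adjusted over the list alone (camera adjusted p = 3.16e-08, adjusted p = 0.269 with an estimated correlation). Ergosterol genes fell in 13 of 23 cases, 13 adjusted over the list alone, led by ERG3 at −1.09 ± 0.16 (camera adjusted p = 1.13e-05, adjusted p = 0.0338 with an estimated correlation). The totals were 1361 genes higher and 1344 lower, or 2160 and 764 with total counts only, which moved the median of all genes by 0.24.

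At 45 min ribosomal protein genes were lower in the mpk1Δ strain than in WT. RPS3 went from 584 ± 130 CPM (SD) in WT to 36.4 ± 13.6 CPM, a change of −4.00 ± 0.36 (edgeR adjusted p = 3.01e-10, all 3 mpk1Δ libraries below all 3 WT libraries), and RPL9A changed by −4.22 ± 0.51. Of the 137 ribosomal protein genes 135 fell, 135 adjusted over the list alone, with a median of −2.83 (camera adjusted p = 2.17e-37, adjusted p = 0.432 with an estimated correlation). Chaperone genes fell in 25 of 27 cases, 25 adjusted over the list alone, with a median of −1.25 (camera adjusted p = 5.18e-07, adjusted p = 0.49 with an estimated correlation). The counts became 15 falling and 1 rising with total counts only, and the median −0.49. HSP104 stood at −1.48 ± 0.25 and SSA4 at −1.40 ± 0.26. Cell wall integrity targets fell in 17 of 25 cases and rose in 1, 18 and 1 adjusted over the list alone, with a median of −1.22 (camera adjusted p = 0.000212, adjusted p = 0.432 with an estimated correlation). That became 10 falling and 5 rising with total counts only, and the median −0.46. The wall glycoprotein gene HSP150 changed by −2.47 ± 0.22 (edgeR adjusted p = 1.91e-10, all 3 below all 3), FKS1 by −2.01 ± 0.17, PIR3 by −1.91 ± 0.31 and PST1 by −1.40 ± 0.21. Proteasome genes rose in 26 of 32 cases and fell in 3, 26 and 3 adjusted over the list alone (camera adjusted p = 4.95e-06, adjusted p = 0.49 with an estimated correlation), with RPN10 at 1.30 ± 0.19. RPN4, which encodes their transcription factor, changed by −1.49 ± 0.29. The phosphate gene PHM6 was still higher by 3.96 ± 0.55. Within the list, 4 of the 15 phosphate genes rose and 5 fell, 4 and 5 adjusted over the list alone (camera adjusted p = 0.799), or 9 and 1 with total counts only. HSP12 and CTT1 did not pass, at 0.55 ± 0.47 and 0.07 ± 0.38, but both passed with total counts only, at 1.37 and 0.86. The totals were 1799 higher and 1895 lower. Total counts moved the median of all genes by 0.76 and gave 3862 higher and 665 lower.

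**Figure D2:**
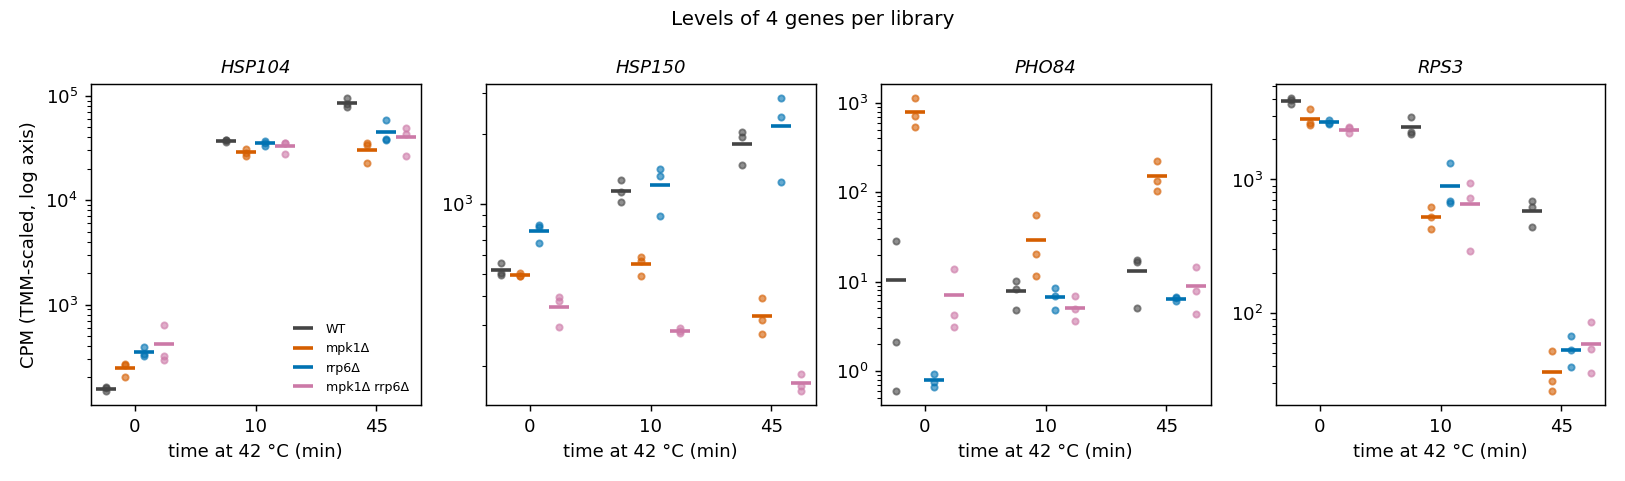
Level of HSP104, HSP150, PHO84 and RPS3 in CPM with TMM scaling (logarithmic vertical axis) against time at 42 °C in min, with strains in colours, dots for libraries and a dash for the mean of 3. At 45 min HSP150 stood at 1817 CPM in WT, 329 CPM in the mpk1Δ strain, 2156 CPM in the rrp6Δ strain and 169 CPM in the double deletion.

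Loss of RRP6 was compared with WT before heat in the same way. TPO2, encoding a polyamine exporter, stood 6.06 ± 0.82 above WT (edgeR adjusted p = 2.22e-06, all 3 rrp6Δ libraries above all 3 WT libraries), and YRO2 5.28 ± 0.53. NRD1, encoding a transcription termination factor, rose by 1.96 ± 0.34. Amino acid biosynthesis genes under Gcn4 rose in 17 of 29 cases, 20 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 9.85e-13, adjusted p = 0.0217 with an estimated correlation). They included ARG1 at 3.45 ± 0.32 of arginine synthesis and LEU1 at 2.12 ± 0.28 of leucine synthesis. General stress genes rose in 13 of 26 cases, 14 adjusted over the list alone (camera adjusted p = 3.9e-11, adjusted p = 0.337 with an estimated correlation). Chaperone genes rose in 10 of 27, 12 adjusted over the list alone (camera adjusted p = 0.000999, adjusted p = 0.599 with an estimated correlation), including HSP104 at 1.15 ± 0.25. Of 12 genes attenuated through Nrd1, 3 rose and none fell, 3 adjusted over the list alone (camera adjusted p = 0.0543). Its members IMD2 and RPL9B did not pass at −0.25 ± 0.22 and −0.33 ± 0.17, though RPL9B passed at −0.33 with only the 6 libraries compared. Cell wall integrity targets rose in 4 of 25 cases and fell in 1, 6 and 1 adjusted over the list alone (camera adjusted p = 0.0597, and 0.0464 with replicate letters as a block), with PIR3 at 1.77 ± 0.42. Total counts alone gave 8 rising and 0 falling. The GTPase activator gene GYP5 changed by −3.18 ± 0.24 and the wall mannoprotein gene TIR1 by −2.76 ± 0.22. The totals were 561 higher and 279 lower. The sum of 840 became 546 without replicate B of WT and 1953 (1037 higher, 916 lower) with only the 6 libraries compared. Total counts moved the median of all genes by 0.18 and gave 930 higher and 84 lower, and DESeq2 gave 602 and 474.

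In heated cells, iron and ergosterol genes were lower in the rrp6Δ strain than in WT. Before heat, the mean level of the ergosterol list in the rrp6Δ strain was −0.221 ± 0.037 (SD, n = 3) relative to unheated WT. That of the iron list was −0.457 ± 0.375, so these differences were not shown to need heat. At 10 min the iron permease gene FTR1 changed by −2.23 ± 0.16 and ERG3 by −1.63 ± 0.17 relative to heated WT, and at 45 min FTR1 by −3.25 ± 0.18 (edgeR adjusted p = 3.97e-14, all 3 rrp6Δ libraries below all 3 WT libraries) and ERG25 by −2.04 ± 0.14. Iron regulon genes fell in 12 of 16 cases at 10 min, 16 adjusted over the list alone, and in 14 at 45 min, 14 adjusted over the list alone, with medians of −1.29 and −1.92 (camera adjusted p = 4.03e-10 and 1.08e-08, adjusted p = 0.0706 and adjusted p = 0.114 with an estimated correlation). Ergosterol genes fell in 16 and 18 of 23 cases, 18 and 19 adjusted over the list alone, with medians of −0.69 and −0.67 (camera adjusted p = 5.87e-12 and 2.16e-07, adjusted p = 0.000237 and adjusted p = 0.00617 with an estimated correlation). Ribosomal protein genes fell in 128 and 126 of 137 cases and rose in 4 each time, 128 and 4 and then 129 and 5 adjusted over the list alone, with medians of −1.42 and −1.84 (camera adjusted p = 4.54e-36 and 1.4e-28, adjusted p = 0.304 and adjusted p = 0.653 with an estimated correlation). TPO2, STP4 and MIG2 were higher at 10 min, by 4.91 ± 0.62, 4.03 ± 0.53 and 3.67 ± 0.42. SLT2 rose by 1.07 ± 0.23 and 1.91 ± 0.24 at the 2 times. Before heat SLT2 stood at 143.5 ± 3.502 CPM (SD, total-count scaling) in the rrp6Δ strain and 75.89 ± 9.257 CPM in WT. At 45 min HSP104 changed by −0.92 ± 0.25, NRD1 by −1.37 ± 0.34 and RPL9A by −4.02 ± 0.52. The totals were 872 higher and 949 lower at 10 min, and 1304 and 1487 at 45 min, where total counts moved the median of all genes by 0.23 and gave 1811 higher and 934 lower.

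The double deletion was compared with WT at each time. Before heat ARG1 stood 4.64 ± 0.32 above WT (edgeR adjusted p = 3.84e-12, all 3 double-deletion libraries above all 3 WT libraries) and HXK1 3.68 ± 0.41, while CWP1 changed by −2.31 ± 0.39 and TIR1 by −3.47 ± 0.24. General stress genes rose in 21 of 26 cases, 22 adjusted over the list alone (camera adjusted p = 6.44e-16, adjusted p = 0.126 with an estimated correlation). Gcn4 targets rose in 17 of 29, 18 adjusted over the list alone (camera adjusted p = 1.1e-10, adjusted p = 0.0542 with an estimated correlation). PHO84 did not pass, at −0.40 ± 0.72, with 28.6, 2.09 and 0.602 CPM in WT libraries A, B and C and 14.0, 4.19 and 3.07 in the double deletion. Without WT library A its change was 2.19 and again did not pass. Of 15 phosphate genes 1 rose and 2 fell, 1 and 1 adjusted over the list alone (camera adjusted p = 0.751), or 2 and 0 with total counts only. The 4 genes specific to mating type alpha gave camera adjusted p = 0.0511, or 0.0358 with replicate letters as a block, and 0.0568 or 0.044 at 45 min. The totals were 891 higher and 698 lower before heat, 1126 and 1113 at 10 min and 1488 and 1648 at 45 min. With only the 6 libraries of each comparison, the sums of 1589, 2239 and 3136 became 2657, 1285 and 1956. Scaled by total counts alone, the median of all genes moved by 0.27, 0.14 and 0.45 and the splits were 1673 and 109, 1396 and 699, and 2743 and 721.

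In the heated double deletion HSP150 changed by −2.01 ± 0.21 at 10 min and −3.43 ± 0.23 at 45 min relative to WT (edgeR adjusted p = 3.29e-12 at 45 min, all 3 below all 3). Cell wall integrity targets fell in 16 and 15 of 25 cases and none rose, 18 and 15 adjusted over the list alone with 1 rising at 10 min, at medians of −0.71 and −0.83 (camera adjusted p = 3.7e-06 and 4.95e-05, adjusted p = 0.164 and adjusted p = 0.344 with an estimated correlation). Ribosomal protein genes fell in 128 of 137 cases at both times and rose in 1, 131 and 129 falling adjusted over the list alone, at medians of −1.63 and −2.04 (camera adjusted p = 3.77e-44 and 5.06e-29, adjusted p = 0.174 and adjusted p = 0.371 with an estimated correlation). All 10 histone genes fell at 10 min, 10 adjusted over the list alone, with a median of −1.05 (camera adjusted p = 2.26e-08, adjusted p = 0.0176 with an estimated correlation), with HTB1 at −1.49 ± 0.14. Ergosterol genes fell in 20 and 17 of 23 cases, 21 and 17 adjusted over the list alone, with 1 rising at 45 min (camera adjusted p = 1.12e-11 and 7.29e-06, adjusted p = 0.000281 and adjusted p = 0.0218 with an estimated correlation). Total counts gave 7 falling and 2 rising at 45 min. At 45 min chaperone genes fell in 15 of 27 cases and rose in 1, 15 and 1 adjusted over the list alone (camera adjusted p = 0.00932, adjusted p = 0.686 with an estimated correlation), with HSP104 at −1.09 ± 0.25. Total counts gave 7 chaperone genes falling and 5 rising. HSP104 did not pass with only the 6 libraries compared, at −1.04 (edgeR adjusted p = 0.0603). The ornithine transaminase gene CAR2 changed by −3.95 ± 0.28.

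Removing MPK1 from a strain already lacking RRP6 lowered cell wall genes at every time. HSP150 changed by −1.09 ± 0.21, −2.09 ± 0.21 and −3.67 ± 0.23 at 0, 10 and 45 min (edgeR adjusted p = 6.61e-13 at 45 min, all 3 double-deletion libraries below all 3 rrp6Δ libraries). Its level at 45 min was 169 ± 14.8 CPM (SD) against 2156 ± 826 CPM. Cell wall integrity targets fell in 14, 12 and 16 of 25 cases, 16, 13 and 18 adjusted over the list alone with 1 rising at 45 min, at medians of −0.63, −0.60 and −1.19 (camera adjusted p = 8.47e-12, 5.77e-12 and 2.53e-20, adjusted p = 0.048, adjusted p = 0.0386 and adjusted p = 0.00304 with an estimated correlation). Before heat 7 of them fell with total counts only. At 45 min PIR3 changed by −3.33 ± 0.33, the wall protein gene SED1 by −3.26 ± 0.31 and PST1 by −2.09 ± 0.22, and before heat CWP1 changed by −3.71 ± 0.39. PHO84 rose before heat by 3.17 ± 0.90. It did not pass without replicate A of the double deletion, at 2.17, or without replicate A, B or C of the rrp6Δ strain, at 3.31, 3.16 and 3.03. Histone genes fell in 6 of 10 cases at 10 min, 8 adjusted over the list alone (camera adjusted p = 7.42e-07, adjusted p = 0.0386 with an estimated correlation), and 3 fell with total counts only. Exosome genes rose in 4 of 19 cases at 10 min, 5 adjusted over the list alone with 1 falling (camera adjusted p = 0.0474, or 0.0601 with replicate letters as a block, and adjusted p = 0.746 with an estimated correlation).

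The 3 comparisons of the double deletion with the rrp6Δ strain gave 344 genes higher and 247 lower at 0 min, 288 and 236 at 10 min and 408 and 364 at 45 min. Before heat the sum of 591 became 393, 364 and 393 without replicate A, B or C of the double deletion, and 362 and 336 without replicate B or C of the rrp6Δ strain. At 10 min the sum of 524 became 294 without replicate A of the double deletion and 308 and 255 without replicate B or C of the rrp6Δ strain, and at 45 min 772 became 454 without replicate A of the rrp6Δ strain. With only the 6 libraries compared the sums were 1668, 51 and 116, the last being 48 higher and 68 lower. Changed members of the lists were not counted in that fit, so the list counts for these comparisons rest on the spread shared over all 12 groups. Total counts moved the median of all genes by 0.13 at 10 min and 0.22 at 45 min and gave 392 and 87, 411 and 89, and 964 and 127. The median of the cell wall list kept its direction under every scaling.

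In the double deletion, which lacks RRP6 as well as MPK1, phosphate genes were lower than in the mpk1Δ strain. A medium difference confined to the mpk1Δ cultures, left open below, would give a difference in the same direction. Before heat PHO84 changed by −6.79 ± 0.67 (edgeR adjusted p = 4.72e-09, all 3 double-deletion libraries below all 3 mpk1Δ libraries), PHO5 by −4.90 ± 0.22 and PHO12 by −4.54 ± 0.24. Without library A of the double deletion PHO84 changed by −7.80. Phosphate regulon genes fell in 13 of 15 cases, 14 adjusted over the list alone, with a median of −2.97 (camera adjusted p = 3.31e-42, adjusted p = 2.96e-07 with an estimated correlation). Gcn4 targets rose in 22 of 29 cases before heat and 19 at 10 min, 24 and 22 adjusted over the list alone, with medians of 0.96 and 0.59 (camera adjusted p = 1.07e-35 and 3.24e-12, adjusted p = 1.71e-05 and adjusted p = 0.0264 with an estimated correlation). ARG1 stood at 4.16 ± 0.29 before heat. NOG2, encoding a GTPase of large-subunit assembly, rose by 3.75 ± 0.36 at 10 min and 4.52 ± 0.35 at 45 min. Ribosome biogenesis genes rose in 19 of 33 cases at 10 min and 13 at 45 min, 22 and 16 adjusted over the list alone (camera adjusted p = 4.51e-12 and 8.6e-06, adjusted p = 0.215 and adjusted p = 0.63 with an estimated correlation). Ribosomal protein genes rose in 51 of 137 cases at 45 min, 51 adjusted over the list alone with 1 falling (camera adjusted p = 1.05e-09, adjusted p = 0.688 with an estimated correlation). With total counts only 16 of these rose and 4 fell, and 7 ribosome biogenesis genes rose at 45 min. PHO84 was still lower at 10 and 45 min, by −2.47 ± 0.67 and −4.15 ± 0.66. At 10 min PHO84 did not pass without replicate A of the mpk1Δ strain, at −1.68 (edgeR adjusted p = 0.0782).

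The double deletion had 281 genes higher and 157 lower than the mpk1Δ strain at 0 min, 692 and 512 at 10 min and 933 and 742 at 45 min. At 10 min the sum of 1204 became 603 without replicate B of the mpk1Δ strain, 584 and 1822 without replicate B or C of the double deletion, and 2034 without both heated double-deletion libraries of letter C. At 45 min 1675 became 934 without replicate B of the double deletion. With only the 6 libraries compared the sums were 924, 317 (238 higher, 79 lower) and 567. Total counts moved the median of all genes by 0.11, −0.10 and −0.31 and gave 351 and 73, 413 and 615, and 323 and 1905. The median of the phosphate list kept its direction under every scaling.

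**Figure D3:**
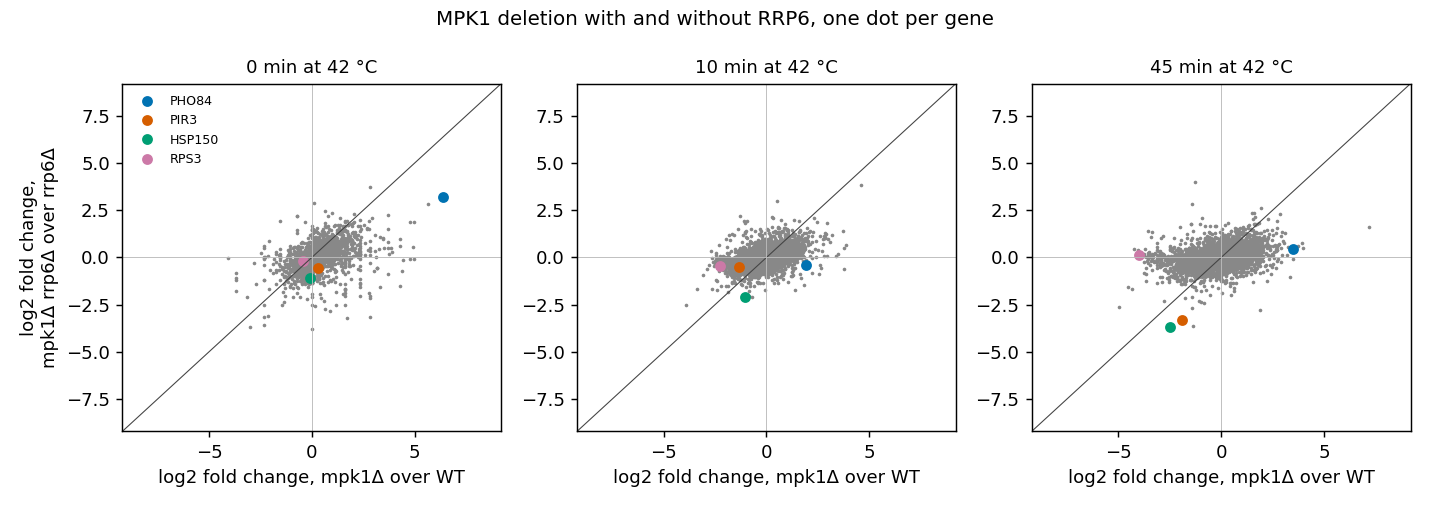
Log2 fold change of each gene in the mpk1Δ strain over WT (horizontal axis) against that in the double deletion over the rrp6Δ strain (vertical axis) at 0, 10 and 45 min, 1 dot per gene, with a diagonal line and PHO84, PIR3, HSP150 and RPS3 coloured. Across genes r was 0.475, 0.429 and 0.374 at the 3 times, and RPS3, at −4.00 on the horizontal axis at 45 min, lay far from the diagonal.

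Heat responses were then compared between strains as differences of differences over 12 libraries each. In the mpk1Δ strain the heat response of PHO84 at 10 min differed from that of WT by −4.48 ± 0.94 (edgeR adjusted p = 0.00151), that of PHO89 by −5.29 ± 0.89 and that of PHO5 by −4.68 ± 0.31. For PHO84 all 3 heated mpk1Δ libraries lay below all 3 unheated ones, while heated and unheated WT libraries overlapped. Without library A of unheated WT the PHO84 difference was −7.08. At 45 min the response of RPS3 differed by −3.56 ± 0.46 (edgeR adjusted p = 8.19e-07), HSP150 by −2.40 ± 0.29, PST1 by −2.42 ± 0.29 and HSP104 by −2.12 ± 0.36. Phosphate genes had a lower response in 13 of 15 cases at 10 min and 14 at 45 min, 14 each time adjusted over the list alone (camera adjusted p = 1.71e-17 and 2.79e-09, adjusted p = 0.000427 and adjusted p = 0.0187 with an estimated correlation). At 45 min the count of 14 phosphate genes became 9 with total counts only. Relative to unheated WT, the mean level of the phosphate list in the mpk1Δ strain was 3.058 before heat. It was 1.658 at 10 min and 1.899 at 45 min, against 1.272 and 1.643 in WT. Ribosomal protein genes had a lower response in 131 and 130 of 137 cases, 134 and 131 adjusted over the list alone (camera adjusted p = 1.52e-36 and 8.47e-28, adjusted p = 0.308 and adjusted p = 0.372 with an estimated correlation). At 45 min general stress genes had a lower response in 18 of 26 cases and chaperone genes in 19 of 27, 19 and 23 adjusted over the list alone (camera adjusted p = 6.05e-08 and 6.73e-07, adjusted p = 0.372 and adjusted p = 0.419 with an estimated correlation). The chaperone count became 11 with total counts only. The mean level of the stress list relative to unheated WT was 1.447 in the unheated mpk1Δ strain. At 45 min it was 6.161 in that strain and 6.393 in WT. The cell wall list had 2 higher and 9 lower of 25 at 45 min, 2 and 10 adjusted over the list alone, with a median of −0.56 that became 0.03 with total counts only (camera adjusted p = 0.0384, adjusted p = 0.475 with an estimated correlation). With total counts only 5 of its genes were higher and 4 lower. The totals were 480 higher and 799 lower at 10 min and 1050 and 1488 at 45 min. At 45 min scaling by total counts moved the median of all genes by 0.60 and gave 2429 and 594.

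In the rrp6Δ strain the heat response of NRD1 at 45 min differed from that of WT by −3.33 ± 0.48, that of the serine synthesis gene SER3 by −2.34 ± 0.24, that of FTR1 by −2.49 ± 0.23 and that of HSP104 by −2.07 ± 0.36, while SLT2 differed by 1.18 ± 0.33. At 10 min NOG2 differed by 2.55 ± 0.44, SER3 by −2.33 ± 0.24 and PIR3 by −2.30 ± 0.53. Ribosomal protein genes had a lower response in 19 of 137 cases at 10 min and 96 at 45 min and a higher one in 3, 60 and 107 lower adjusted over the list alone (camera adjusted p = 4.94e-14 and 3.59e-14, adjusted p = 0.754 and adjusted p = 0.797 with an estimated correlation). The count of 19 became 51 with total counts only and 12 with DESeq2's size factors. Genes attenuated through Nrd1 had a lower response in 7 of 12 cases at 45 min and a higher one in 1, 8 and 1 adjusted over the list alone (camera adjusted p = 0.00142, adjusted p = 0.335 with an estimated correlation). The totals were 288 higher and 504 lower at 10 min and 759 and 1178 at 45 min. The sum of 792 at 10 min became 526 without replicate B of unheated WT. With total counts only, the median of all genes at 10 min moved by −0.17 and the split was 91 and 721.

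Non-additivity was measured as the double deletion minus both single deletions plus WT, again over 12 libraries. Before heat PHO5 differed from the sum of the single deletions by −5.05 ± 0.34 (edgeR adjusted p = 1.46e-11), TPO2 by −4.88 ± 1.10 and YGP1 by −4.88 ± 0.48, and PHO84 did not pass at −3.21 ± 1.38. Without replicate A of WT, PHO84 passed at −5.81 (edgeR adjusted p = 0.0257). TPO2 did not pass without replicate A or B of WT, at −4.69 and −4.61, or without replicate C of the mpk1Δ strain, at −4.46, and lay at −6.36 without replicate C of the double deletion. Phosphate genes were below additivity in 12 of 15 cases, 15 adjusted over the list alone, with a median of −3.10 (camera adjusted p = 4.44e-61, adjusted p = 8.14e-09 with an estimated correlation). At 45 min RPS3 lay 4.15 ± 0.48 above additivity (edgeR adjusted p = 2.73e-07) and HSP104 1.30 ± 0.35, while PIR3 lay at −1.42 ± 0.44. PIR3 did not pass without replicate C of the rrp6Δ strain, at −0.81, or with only the 12 libraries compared, at −1.46. Ribosomal protein genes lay above additivity in 131 of 137 cases at 10 min and 130 at 45 min, 135 and 132 adjusted over the list alone, with medians of 1.87 and 2.60 (camera adjusted p = 1.1e-49 and 8.3e-44, adjusted p = 0.289 and adjusted p = 0.53 with an estimated correlation). Ergosterol genes lay above it in 10 of 23 cases at 10 min, 13 adjusted over the list alone (camera adjusted p = 1.53e-05, adjusted p = 0.0324 with an estimated correlation), and 6 did so with total counts only. General stress genes lay below it in 16 of 26, 20 adjusted over the list alone (camera adjusted p = 6.71e-12, adjusted p = 0.289 with an estimated correlation). Glycolysis genes before heat gave camera adjusted p = 0.0721, or 0.0492 with replicate letters as a block. The totals were 10 above and 52 below at 0 min, 611 and 399 at 10 min, and 1295 and 1012 at 45 min. At 10 min the sum of 1010 became 536 without replicate B of WT, 581 without replicate B of the mpk1Δ strain, 630 without replicate C of the rrp6Δ strain, 488 and 1623 without replicate B or C of the double deletion, and 1801 without both heated double-deletion libraries of letter C. With only the libraries compared the sums were 211 (71 above, 140 below), 177 and 1489. The use of total counts moved the median by −0.11 at 10 min and −0.53 at 45 min and gave 339 and 372, and 450 and 2430.

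The effects of the deletions were also compared across 6015 genes, which are not independent replicates. The mpk1Δ and rrp6Δ strains, both against the same WT libraries, shared 197, 975 and 1896 genes changed in the same direction at 0, 10 and 45 min and 46, 123 and 132 in opposite directions. Among them 133, 403 and 856 were higher in both, against 56, 197 and 390 if the sets were independent, and 64, 572 and 1040 were lower in both, against 14.5, 212 and 468. Part of this excess can come from the shared WT libraries. The covariance of the 2 effects was 0.19, 0.258 and 0.547, against 0.0975, 0.036 and 0.0489 in simulations with shared controls alone, leaving 0.0923, 0.222 and 0.499. Each gene was drawn independently, so deviations of the WT libraries common to many genes were absent from the simulations. What was left can therefore still come in part from the shared WT libraries. The correlation r was 0.339, 0.457 and 0.633 against simulated values of 0.667, 0.48 and 0.606. The MPK1 effect in WT and in the rrp6Δ background, which share no libraries, had 330, 302 and 490 genes in the same direction and 3, 16 and 62 in opposite directions. HSP150, CWP1 and PIR3 were among those lower in both backgrounds at 45 min, at −2.47 ± 0.22 and −3.67 ± 0.23 for HSP150 and −1.91 ± 0.31 and −3.33 ± 0.33 for PIR3. The RRP6 effect in WT and in the mpk1Δ background had 297, 440 and 566 genes in the same direction and 0, 40 and 223 in opposite directions, with r across genes of 0.729, 0.506 and 0.203.

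Reads outside the counted open reading frames, called reads outside genes here, were expressed per 100 reads assigned to genes. The same was done for reads aligned to several places. The files held no entries for stable non-coding RNAs, so reads over such genes could fall among the reads outside genes. In WT the reads outside genes went from 2.62 ± 0.159 (SD, n = 3) at 0 min to 5.40 ± 0.797 at 10 min and 8.80 ± 0.734 at 45 min. In the rrp6Δ strain they were 7.65 ± 0.594, 12.1 ± 0.994 and 16.1 ± 1.81, with all 3 libraries above all 3 WT libraries at each time (exact permutation p = 0.1, the smallest possible with 3 against 3). Reads aligned to several places were 6.49 ± 0.305, 6.45 ± 0.599 and 10.9 ± 2.78 in WT and 16.4, 33.0 and 45.6 in the rrp6Δ strain, again with p = 0.1 in the exact test at each time. Over all strains and times, deletion of RRP6 moved reads outside genes from 6.51 to 11.3 and multiply aligned reads from 7.19 to 27.9 per 100, with the groups apart in 6 of 6 strata (permutation p = 1e-05, the smallest possible with 100000 resamples). Deletion of MPK1 moved multiply aligned reads from 19.8 to 15.3 (permutation p = 5e-05) and reads outside genes from 8.78 to 9.03 (permutation p = 0.6). By time, reads outside genes were 2.83, 6.15 and 13.3 in the mpk1Δ strain, at 45 min with all 3 libraries above all 3 WT libraries (exact permutation p = 0.1), and 6.48, 10.8 and 14.6 in the double deletion. Multiply aligned reads were 6.16, 5.96 and 7.20 in the mpk1Δ strain and 13.6, 22.8 and 36 in the double deletion. The mpk1Δ strain thus differed from WT by −0.33, −0.497 and −3.679 (exact permutation p = 0.5, 0.4 and 0.1). The double deletion differed from the rrp6Δ strain by −2.801, −10.236 and −9.529 (exact permutation p = 0.3, 0.1 and 0.2).

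**Figure D4:**
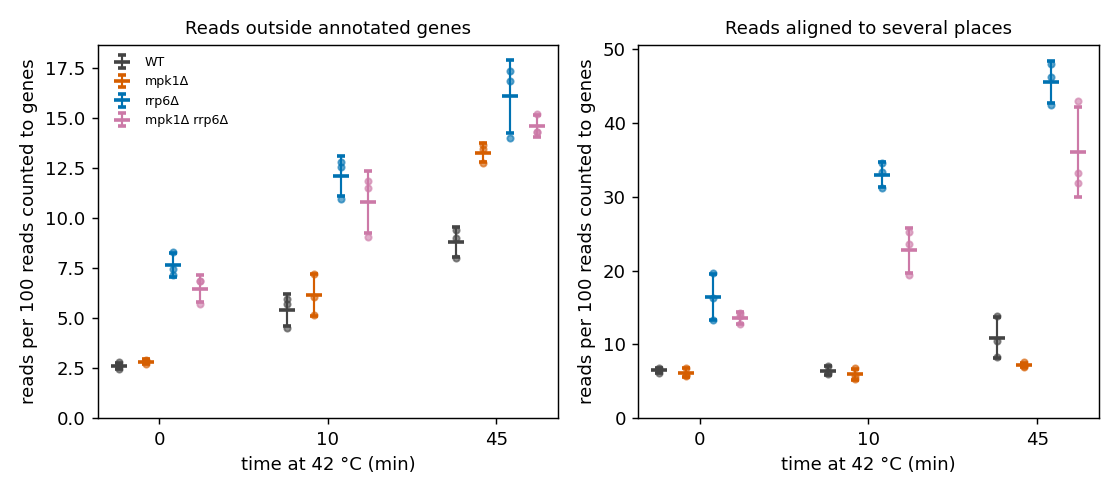
Reads outside the counted open reading frames (left, titled as outside annotated genes) and reads aligned to several places (right) per 100 reads counted to genes, against time at 42 °C in min. The 4 strains are shown with dots for libraries and bars for the mean ± SD (n = 3). At 45 min the multiply aligned reads stood at 10.9 in WT, 7.2 in the mpk1Δ strain, 45.6 in the rrp6Δ strain and 36 in the double deletion.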

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

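All explanations weighed in this part were tested only after the results had been seen. The first 12 results below stood out because an effect differed between strains by a direct test of the difference, and the last 8 because a signal appeared in the read categories outside the gene counts.

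Heat responses of the mpk1Δ strain and WT differed for 1279 genes at 10 min and 2538 at 45 min. Those of the rrp6Δ strain and WT differed for 792 genes at 10 min and 1937 at 45 min. Departure from additivity in the double deletion was found for 62 genes at 0 min, 1010 at 10 min and 2307 at 45 min. Ergosterol genes had a median difference in heat response of −0.58 in the mpk1Δ strain at 10 min, and phosphate genes of −2.32 at 10 min and −1.80 at 45 min. The double deletion departed from additivity by a median of −3.10 for phosphate genes at 0 min and 0.43 for ergosterol genes at 10 min. Reads outside the counted open reading frames, per 100 counted reads, were 6.183 higher in WT at 45 min than at 0 min, and 5.032, 6.719 and 7.287 higher in the rrp6Δ strain than in WT at 0, 10 and 45 min. Reads aligned to several places were 4.384 higher in WT at 45 min than at 0 min, and 9.933, 26.542 and 34.687 higher in the rrp6Δ strain than in WT.

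Phosphate genes were higher in the mpk1Δ strain than in WT at 0 min and not in the double deletion. Scaling between libraries did not account for it, since the median with total counts only was 3.27. In the double deletion 21 of 26 general stress genes rose while the phosphate median was 0.09, so higher stress genes did not go with higher phosphate genes there. That did not exclude a growth state raising both in the mpk1Δ strain, since the double deletion also lacks RRP6. A medium difference confined to the mpk1Δ cultures could still be the cause, as could loss of the kinase, and the median of 0.10 at 45 min did not separate the explanations.

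Ribosomal protein genes were lower in the mpk1Δ strain than in WT after 45 min of heat. With total counts only their median was −2.08, so scaling was not the whole cause. Had the WT cultures been heated less or sampled earlier, chaperone genes were predicted to be higher in the mpk1Δ strain. Their highest median over 4 scalings was −0.49, which could not decide it, since chaperone levels did not keep rising in that strain. Relative to unheated WT the mean level of the list was 4.908 at 10 min and 4.752 at 45 min there, against 5.105 and 5.879 in WT. Members with no A or B suffix, 19 of the 137, had a median of −3.02, so reads shared between duplicated genes were not the cause. Loss of the kinase alone did not describe the pattern, since the rrp6Δ strain and the double deletion also lay below the same WT libraries, at medians of −1.84 and −2.04, and removing MPK1 in the rrp6Δ background gave 1 rising and 6 falling at a median of −0.01, or 0.18 with total counts only and 0.01 with DESeq2's size factors, so the explanation stayed open.

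Reads aligned to several places were more frequent in libraries of strains lacking RRP6. Without the 5 most abundant genes the difference was 25.023 per 100 counted reads, which decided nothing, since leaving out counted reads raises the ratio in every library. Within replicate letters the lowest of the 3 differences was 17.65, so the difference did not rest on the libraries of 1 letter. Each letter held all 12 groups, so that letters were balanced by design. Loss of the nuclease remained among the open explanations, and which transcripts the reads came from was not analysed here.

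For the 23 comparisons of 3 libraries against 3, all 10 splits of the samples were fitted. The other 7, the differences in heat response and the non-additivity, use 12 libraries, and of their many splits only 10 were fitted, those that relabelled both pairs of groups alike. In each comparison 1 of 10 splits, the real one, gave as many called genes, and 10 splits are too few for a share under 0.05. For heat at 10 and 45 min the real counts were 4481 and 4827 in WT, 4654 and 4928 in the mpk1Δ strain, 4503 and 4781 in the rrp6Δ strain, and 4493 and 4681 in the double deletion, and the highest other was 0, except 1 for the mpk1Δ strain at 10 min and 1 for the double deletion at 45 min. At 0, 10 and 45 min the mpk1Δ strain against WT gave 915, 2705 and 3694 with highest others of 0, 17 and 69, and the rrp6Δ strain 840, 1821 and 2791 with 0, 0 and 21. The double deletion gave 1589, 2239 and 3136 with 0, 369 and 245 against WT, 591, 524 and 772 with 10, 233 and 381 against the rrp6Δ strain, and 438, 1204 and 1675 with 0, 247 and 530 against the mpk1Δ strain. For differences in heat response the highest other was 0 in all 4 comparisons, and for non-additivity it was 0, 0 and 52.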

How the results depend on the processing

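The alternative without both heated double-deletion libraries of letter C was chosen only after the results had been seen. Counts of changed genes stayed within 1.5 times in all 30 comparisons with DESeq2, DESeq2's size factors, a mean of at least 5 CPM, no low-count filter, protein-coding genes only, a replicate block and total counts only. Such counts sum both directions and cannot show a shift between higher and lower genes. Total counts moved the median of all genes by 0.76 for the mpk1Δ strain against WT at 45 min, and changed the splits given above. Of all repeated counts 433 stayed and 39 moved. A fit of only the samples of the comparison estimates the spread from fewer libraries and from those groups alone. The main fit shares it over all 12 groups, though replicates were not equally close in all of them. Replicates B and C of the double deletion correlated with r of 0.994 at 0 min and 0.958 at 10 min. With only the samples of the comparison, the counts at 0 min became 2267 for the mpk1Δ strain and 1953 for the rrp6Δ strain against WT. They became 2657, 1285 and 1956 for the double deletion against WT at 0, 10 and 45 min, 1668, 51 and 116 against the rrp6Δ strain, 924, 317 and 567 against the mpk1Δ strain, and 211, 177 and 1489 for non-additivity. Without both letter C libraries, the double deletion against the mpk1Δ strain at 10 min gave 2034 genes and non-additivity at 10 min 1801, and the cause was not tested. Leaving out 1 library gave 523 to 737 for the mpk1Δ strain and 546 to 690 for the rrp6Δ strain against WT at 0 min. It gave 336 to 426, 255 to 497 and 454 to 760 for the double deletion against the rrp6Δ strain at 0, 10 and 45 min, and 584 to 1822 and 934 to 2043 against the mpk1Δ strain at 10 and 45 min. It gave 526 to 946 for the heat response of the rrp6Δ strain at 10 min and 488 to 1623 for non-additivity at 10 min, and the cause was not tested. At 2-fold or more, where fewer genes pass by construction, genes in the same direction at 0, 10 and 45 min numbered 59, 246 and 566 for the mpk1Δ and rrp6Δ strains against WT. They numbered 57, 48 and 85 for the 2 MPK1 effects, 149, 119 and 87 for the 2 RRP6 effects, 235, 351 and 705 for the rrp6Δ strain and the double deletion against WT, and 148, 391 and 825 for the mpk1Δ strain and the double deletion. Without the 2-fold bound the last 2 overlaps held 587, 1275 and 2195 genes, and 652, 1484 and 2464. Both share the WT libraries, which can raise such counts, and had no simulated value. For the 153 results on genes named with a fold change, 2276 repeats kept their call, 11 became weaker, 8 became stronger and none reversed. Of 660 list results none reversed in the list tests, which were not repeated with another scaling method. The median of a list with at least 1 changed member reached or crossed 0 in 87 cases with total counts only, 20 with DESeq2's size factors and 4 with protein-coding genes. With an estimated correlation 343 kept their call and 317 became weaker, with the fry test 524 kept it, 86 became stronger and 50 weaker, and with protein-coding genes 644 kept it, 11 became stronger and 5 weaker. With a replicate block 655 kept it, 4 became stronger and 1 weaker, for example exosome genes in the double deletion against the rrp6Δ strain at 10 min at adjusted p = 0.0601 in camera, and the block changed no other call. In the 25 comparisons whose letters did not pair, the lowest same-letter correlation was −0.372, and over all comparisons the median was 0.105 against −0.052 for other letters. The second median was no independent baseline, since deviations within a group sum to 0, which ties it to the first. The 2 read-category results kept their direction without the 5 most abundant genes, which raises both ratios by construction. Depth limited the weakest genes, since 3 counts in the smallest library correspond to 1.342 CPM.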

Other observations

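Genes specific to the other mating type were counted at low levels in this mating type alpha strain and rose with heat in WT. STE2, the receptor gene of mating type a, stood at 5.30 ± 1.68, 20.1 ± 3.27 and 25.4 ± 5.43 CPM (SD, n = 3) at 0, 10 and 45 min. All 7 genes of that list rose at both times, 7 adjusted over the list alone (camera adjusted p = 0.00678 and 0.00513, adjusted p = 0.156 and adjusted p = 0.154 with an estimated correlation). All 4 alpha-specific genes fell, 4 adjusted over the list alone, with medians of −1.58 and −3.90 (camera adjusted p = 0.0993 and 0.0247, adjusted p = 0.38 with an estimated correlation at 45 min), among them the pheromone gene MF(ALPHA)1 at −3.86 ± 0.46 at 45 min. Meiosis genes rose in 17 and 18 of 20 cases in WT, 17 and 18 adjusted over the list alone, with medians of 1.96 and 2.69 (camera adjusted p = 0.000221 and 9.07e-05, adjusted p = 0.00922 and adjusted p = 0.00542 with an estimated correlation). The share of counted reads on the 683 open reading frames that matched no reference locus tag also rose with heat in WT. It was 0.0736% at 0 min, 0.2635% at 10 min and 0.2455% at 45 min. A rise with heat was thus not particular to the mating type a and meiosis lists. Pheromone response genes fell in 11 of 16 cases and rose in 2 at 10 min, 11 and 2 adjusted over the list alone (camera adjusted p = 0.0303, adjusted p = 0.639 with an estimated correlation).

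Read-through of snoRNA transcripts was a hypothesis written before its result was seen, with 2 tests in the rrp6Δ strain against WT at 0 min. The 21 genes downstream of a snoRNA on the same strand had a median of 0.03 (interval −0.25 to 0.42), with 3 rising and 1 falling. In limma's camera this gave adjusted p = 0.74 over the 2 tests. The 8 genes hosting snoRNAs in introns had a median of −0.34 (interval −0.81 to 0.42), with 0 rising and 1 falling. The direction was downward, opposite to the hypothesis, with adjusted p = 0.037 over the 2 tests in limma's camera, and adjusted p = 0.64 with an estimated correlation. The downstream test met the condition written against read-through, but the interval of its median reached 0.42, so read-through was not excluded. The host test met neither condition. Hosts included ribosomal protein genes and the ribosome assembly gene NOG2. The mean level of the ribosomal protein list at 0 min, relative to WT, was −0.407 in the rrp6Δ strain and −0.55 in the double deletion. A fall of the hosts could therefore not be told apart from a fall of that class. Other comparisons were picked only after the values were seen, and in them the hosts went both ways. In the double deletion 5 rose and 0 fell against the mpk1Δ strain at 45 min, with a median of 1.16, while 0 rose and 6 fell against WT at 0 min, with a median of −0.72. Over all 18 such tests camera gave adjusted p = 3.2e-06 and adjusted p = 0.0019, or adjusted p = 0.56 and adjusted p = 0.6 with an estimated correlation.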
